A study of Mus musculus with 2 samples.

How the data were processed

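Chromatin immunoprecipitation with an antibody to H3K4me2 was followed by sequencing in 2 pools of mouse neural tube (strain B6NCrl, embryonic day 11.5). Per the labels, replicate 1 was made from 109 embryos and replicate 2 from 88 embryos, and they are biological replicates of 1 group. The group and replicate number of each sample were taken from the submitters' labels.

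The starting point was 4 deposited peak lists in narrowPeak format on mm10. Per the notes deposited with the samples, each replicate's list and the pooled list were made from the alignments together with 2 further input files whose role is given only by accession, and the replicated list was made from both replicates' lists and the pooled list. The aligner, the peak caller, its threshold and the replication rule were not given in the sources used here. The fold of each peak (a linear ratio in the signal column of the format, taken as enrichment over the control) is the authors' value, as are the deposited −log10 q values. The deposited −log10 p values were not used here. The deposited score column runs from 10 to 1000 and was not used in any result. Folds and q were used only to describe, rank or filter peaks within 1 list. No file gives read counts, so the depth per sample is unknown, no interval on a fold could be given, and the intervals printed cover counting error of peaks only.

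Gene positions came from the GENCODE M21 comprehensive annotation and sequence from the GRCm38 assembly, the same build as mm10. No peak extended past the end of its chromosome in that assembly. Chromosomes 1 to 19, X and Y were used where a gene or sequence was needed. The annotation has 21938 protein-coding genes on these chromosomes and 132629 distinct TSSs of genes of any kind. A gene was called marked when a replicated peak came within 1 kb of any of its TSSs. Breadth was the length covered by replicated peaks within 10 kb on each side of the 5'-most TSS. Distal peaks had their nearest edge more than 1 kb from every TSS, and each was assigned by its midpoint to the nearest protein-coding TSS within 100 kb. A promoter was CpG-rich when the observed over expected CpG was at least 0.6 and the GC content at least 50% within 500 bp of the 5'-most TSS. A peak's location was that of its midpoint, in the order promoter, exon, intron, intergenic.

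The design, the tests, the main alternatives and 21 gene lists with 457 distinct genes (13 in more than 1 list) were fixed before the data were examined, from textbook knowledge of the tissue and of tissues near it. 1 symbol, the liver gene Tf, was matched through a synonym to Trf. Named genes followed a rule fixed with them. It took from each list the 2 members with the most covered length and up to 2 members, in alphabetical order, with no replicated peak at a TSS, then the genes in the 20 longest joined regions, and for promoters marked in 1 replicate only the 5 listed genes with the highest fold in each direction. Other genes named as examples, such as single Hox genes, Sox2, Shh, Pou5f1 and the marked blood genes, were chosen after their values were seen.

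Overlap between lists meant at least 1 bp. Random expectation came from 100 placements with bedtools 2.31.1 shuffle on the same chromosome, which does not exclude assembly gaps or repeats and so places some peaks where none could be called. Promoter marking of each list was tested with a two-sided Fisher exact test against all other protein-coding genes. Breadth and distal peaks were tested with two-sided permutation tests against 100000 random lists of the same size. The Benjamini-Hochberg adjustment ran over the 21 lists for each measure, with a threshold of 0.05. Genes are not replicates, and neighbouring genes can share peaks, so these p-values describe the lists in these 2 pools. String counts took both strands, and each ratio was ranked among all distinct rearrangements of the same letters without a CG. The work used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and pysam 0.24.0.

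The code was tested on simulated data first. Interval arithmetic gave 0 mismatches with a base-by-base count over 1500 intervals. In simulations with 20000 genes, 98% of 200 changed lists were called for promoter marking and 100% for breadth, and 0.5% of 200 unchanged lists were called higher in each. The simulated genes were independent, without CpG classes or shared peaks, and the changed lists were given a large effect. These rates therefore do not carry over to smaller effects or to lists of neighbouring genes.

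The alternatives tried were each replicate's own list, the pooled list, peaks with −log10 q of at least 5, stricter overlap, other windows, other backgrounds and other joining distances, and, added after the data were seen, the basic annotation, a background of genes with a CpG-poor promoter and 1 value per Hox cluster. The closing section gives their effect. After their results were seen, 2 tests of explanations were replaced. A test of mesenchymal genes taken from the somite list, which had itself passed, gave way to mesenchymal genes outside the 21 lists, and the test of neural microRNA genes was run without the Mir9 genes that had prompted it. The 13 replicated peaks on unplaced scaffolds entered the counts of peaks and overlap but no result that needs a gene.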

Results

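H3K4me2, the dimethylation of lysine 4 of histone H3 that is known from active and poised promoters and from enhancers, was profiled by chromatin immunoprecipitation and sequencing in the neural tube of mouse embryos at day 11.5. The neural tube is the embryonic precursor of the brain and spinal cord, and at this age it holds dividing progenitors beside young neurons. There was 1 group of 2 biological replicates. Replicate 1 was a pool of tissue from 109 embryos and replicate 2 a pool from 88 embryos, both of mixed sex. No other condition was included, so the design asks where the mark lies in this tissue and how well the 2 pools match. The data were 4 peak lists on the mm10 build, namely 1 for each replicate, 1 for the pooled replicates and 1 of peaks that passed a replication filter (the replicated list). The files hold no read counts, so the depth of each library is unknown, and the fold and −log10 q of each peak are the authors' own values.

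H3K4me2 covered about the same part of the genome in both pools. Replicate 1 had 43773 peaks over 41.7 Mb and replicate 2 had 42413 peaks over 38.8 Mb. The replicated list held 30835 peaks over 39.4 Mb, which is 1.45% of the assembled chromosomes. Its peaks had a median width of 1000 bp, against 552 bp in replicate 1 and 555 bp in replicate 2, and the longest, over the Hoxb genes, reached 79542 bp. The median fold was 11.5 in the replicated list, 5.92 in replicate 1 and 5.97 in replicate 2. In the replicated list 352 peaks had a q above 0.05, so the authors' threshold was not a q of 0.05. These numbers describe each list and were not tested.

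The 2 pools shared their strong peaks and differed in their weak ones. Of the peaks of replicate 1, 31345 (71.6%, 95% exact binomial interval 71.2 to 72.0) were overlapped by at least 1 bp of a replicate 2 peak. Of those of replicate 2, 33213 (78.3%, interval 77.9 to 78.7) were overlapped by replicate 1. Placing the other list at random positions on the same chromosomes 100 times gave 3.17% ± 0.0949 (SD) and 3.28% ± 0.0805. In the strongest fold quartile of each list every peak was shared, while in the weakest quartile 28.5% of replicate 1's peaks and 40.8% of replicate 2's were. The peaks found in 1 pool alone were narrow, with median widths of 220 bp in replicate 1 and 207 bp in replicate 2, and weak, with median folds of 3.43 and 3.32. By length, 34.4 Mb was covered in both pools, 0.747 of the 46.0 Mb covered in either. Requiring that 1 peak of each list cover 50% of the other lowered the shares to 58.1% and 59.98%.

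**Figure D1:**
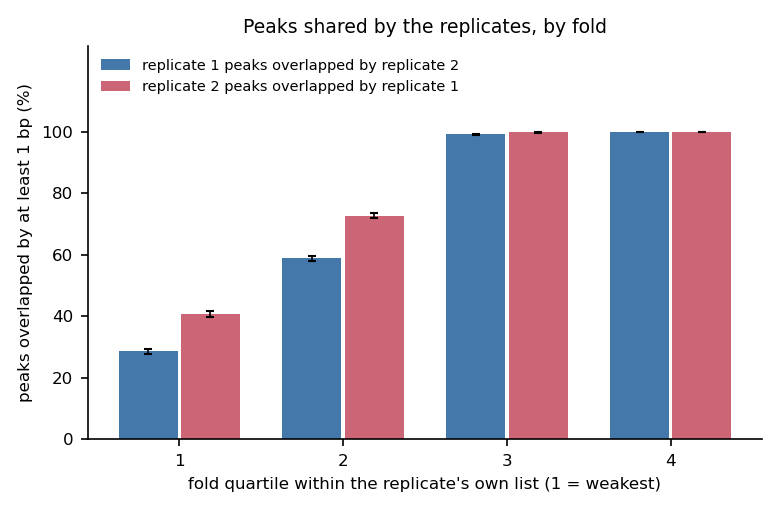
Bars give the percentage of peaks overlapped by at least 1 bp of the other replicate's peaks, for each fold quartile within a replicate's own list, and error bars give 95% exact binomial intervals. The share was 28.5% and 40.8% in the weakest quartile and 100% in the strongest quartile of both lists.

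The replicated list was an exact subset of the pooled list. It held 30835 of the 34885 pooled peaks (88.4%), each with identical start and end. The 4050 pooled peaks outside it had a median fold of 2.97 and a median width of 221 bp, and 3858 of them were in the weakest fold quartile of the pooled list. Among the replicated peaks 28988 overlapped peaks of both replicates, 1838 overlapped those of 1 replicate and 9 overlapped none. The replicated list therefore did not require a peak in each replicate's own list, and the rule behind it was not given in the sources used here.

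H3K4me2 lay mainly at promoters. Of the 30822 replicated peaks on assembled chromosomes, 18617 (60.4%) had their midpoint within 1 kb of an annotated transcription start site (TSS), against 6.22% ± 0.111 (SD) over 100 random placements. Introns held 19.2% of the peaks (39.2% ± 0.284 at random), intergenic sequence 15.8% (51.3% ± 0.297) and exons 4.61% (3.31% ± 0.0887). Promoter peaks were wide and strong, with a median width of 1384 bp and a median fold of 17.3. Intronic peaks had a median width of 471 bp and a fold of 4.22, and intergenic peaks 562 bp and 5.30. Across fold quartiles of the replicated list the promoter share went from 23.96% in the weakest to 89.2% in the strongest. In the replicates' own lists, which keep more weak peaks, the promoter share was 49.2% and 51.4%. For the replicated list with a window of 500 bp it was 45.8%.

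At least 1 TSS of 14489 of 21938 protein-coding genes (66.05%) had a replicated peak within 1 kb, called marked from here on. Nearly all genes with a CpG-rich 5'-most promoter were marked (9616 of 9740, 98.7%). Of the genes with a CpG-poor one 4873 of 12198 (39.9%) were, at that TSS or another. The genes of neural progenitors and neurons were marked almost without exception. Among the lists fixed before the data were examined, all 30 neural progenitor genes were marked, among them Sox2 and Pax6, transcription factors of the ventricular zone. So were 29 of 30 genes of the dorsoventral progenitor domains, such as Shh, the floor plate ligand, and Pax3, a dorsal transcription factor. The lists of postmitotic cells followed, with 31 of 32 spinal interneuron genes, 17 of 18 spinal motor neuron genes and 33 of 34 pan-neuronal genes marked. All 30 signalling ligands and receptors and all 24 housekeeping genes were marked. Each of these lists was marked more often than the other protein-coding genes by a two-sided Fisher exact test with Benjamini-Hochberg adjustment over 21 lists, with adjusted p of 4.2e-05 for the progenitor and signalling lists, 0.000325 for the dorsoventral list, 0.00015 for interneurons, 0.0183 for motor neurons, 0.000146 for pan-neuronal genes and 0.000283 for housekeeping genes. These p-values are over genes, which are not replicates, and describe these 2 pools. With peaks of −log10 q of at least 5 the interneuron share fell to 84.4% (adjusted p = 0.0432, the same exact test). The progenitor, dorsoventral, motor neuron and pan-neuronal lists kept 93.3% or more there. Among genes with a CpG-rich promoter alone, none of the 19 lists with such members was marked more often than the rest, and none at an unadjusted p under 0.05 either, because 98.7% of that background was marked. Among genes with a CpG-poor promoter, a comparison added after the data were seen, the progenitor (8 of 8, adjusted p = 0.00303), dorsoventral (9 of 9, 0.00181), pan-neuronal (17 of 18, 3.9e-05), signalling (9 of 9, 0.00181) and housekeeping (4 of 4, 0.0445) lists passed the same exact test. The motor neuron and interneuron lists, each with 5 of 6 marked, did not pass it there (adjusted p = 0.061, exact test).

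The unmarked members of the neural lists were single genes. Dbx1, a transcription factor of the dorsoventral progenitor domains, and Phox2b, known from hindbrain motor and autonomic neurons, had no peak within 1 kb of a TSS in either replicate. With each replicate's own list 28 of the 30 dorsoventral genes were marked, and 2 genes, Dbx1 among them, were marked in neither. Vsx2, a transcription factor of V2a interneurons, and Dcx, a microtubule protein of young neurons, had none in the replicated list and a peak in each replicate's own list. Peaks nonetheless covered 2.54 kb within 10 kb of the Dcx TSS (chromosome X, 143933311).

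Regional lists were each tested against other protein-coding genes and not against each other. All 12 genes of Hox groups 1 to 4 were marked (adjusted p = 0.0183, Fisher exact test). So were all 15 of groups 5 to 9 (adjusted p = 0.00786, Fisher exact test). In groups 10 to 13, 11 of 12 were marked (adjusted p = 0.0924, Fisher exact test). The exception was Hoxc12, which had a peak in each replicate's own list, and with either of those lists the group passed the test. These peaks did not overlap each other (chromosome 15, 102936467 to 102936798 in replicate 1 and 102936815 to 102936999 in replicate 2). Of the genes that pattern the forebrain and midbrain, 24 of 26 were marked (adjusted p = 0.00653, Fisher exact test), with Otx2 unmarked in both replicates and Tbr1 marked in replicate 1 only. The forebrain and midbrain result did not pass with peaks of −log10 q of at least 5 (76.9%, adjusted p = 0.373) or when only the 5'-most TSS counted (80.8%, 0.0878), by the same Fisher exact test. Neural crest and sensory ganglion genes were marked in 21 of 24 cases (adjusted p = 0.0441), the exceptions being Phox2b and the catecholamine enzymes Dbh and Th, and the call was lost with a 500 bp window (83.3%, adjusted p = 0.118) and with only the 5'-most TSS (75%, 0.34), all by Fisher exact tests. The glial list did not differ from other genes, with 15 of 22 marked (adjusted p = 1, Fisher exact test). Its unmarked members included Gfap and Aqp4, genes of mature astrocytes.

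Genes of blood, liver and the germline were marked less often than other genes. In the liver list 1 of 18 genes was marked (adjusted p = 2.69e-06, Fisher exact test), and the exception was Trf, the transferrin gene. In the blood and microglia list 5 of 22 were marked (adjusted p = 0.00015, the same exact test), namely Gypa, Klf1, Epor, Ikzf1 and Slc4a1. These 6 genes were named after their values were seen. In the pluripotency and germline list 7 of 22 were marked (adjusted p = 0.00279, the same exact test), with Pou5f1 and Nanog among the unmarked. No member of the blood or liver list has a CpG-rich promoter, and 39.9% of all genes with a CpG-poor promoter were marked. Against those genes alone the liver list was still lower (adjusted p = 0.00903, Fisher exact test), while the blood list (22.7%, 0.157) and the CpG-poor part of the pluripotency and germline list (5 of 16, 0.643) did not pass. Against CpG-rich promoters alone the pluripotency and germline list was lower, with 2 of 6 marked (adjusted p = 7e-06, Fisher exact test).

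The lists of 5 other tissues did not pass against all protein-coding genes. Marked were 23 of 27 somite, sclerotome and skeletal muscle genes (adjusted p = 0.057), 12 of 20 endothelial genes (0.744), 10 of 16 notochord and early endoderm genes (0.857), 8 of 16 heart genes (0.237) and 14 of 20 epidermal genes (0.857), all by the same exact test. The somite list passed when replicate 1's own peaks were used (88.9%, adjusted p = 0.0186) and when only the 5'-most TSS counted (85.2%, adjusted p = 0.0275), again by the exact test. It also passed with a 2.5 kb window (88.9%, adjusted p = 0.0179), with the basic annotation (85.2%, 0.0374) and against CpG-poor promoters alone (10 of 14, 0.0445), by the same exact test. Among CpG-rich promoters alone the notochord and early endoderm list was lower, with 5 of 7 marked (adjusted p = 0.0308, Fisher exact test).

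H3K4me2 spread far around the TSSs of neural genes. Random lists of protein-coding genes had a mean of about 1.87 kb covered by replicated peaks within 10 kb on each side of the 5'-most TSS. Neural progenitor genes had 8.64 kb (SD 4.63 over 30 genes), or 8.80 kb with replicate 1's peaks and 8.28 kb with replicate 2's. The widest were Pou3f2 (19.3 kb in the replicated list and 19.1 ± 0.195 kb in the replicates, SD, n = 2) and Pou3f3 (19.3 kb and 19.1 ± 0.301 kb, SD, n = 2), POU-domain factors of neural progenitors. Spinal interneuron genes had 5.66 kb, dorsoventral genes 5.57 kb, motor neuron genes 5.07 kb, signalling genes 4.75 kb and pan-neuronal genes 4.53 kb. In these lists the leading genes were Lhx5 (14.3 kb) and Lhx1 (13.3 kb) of interneurons, Pax3 (17.2 kb) and Irx5 (14.1 kb) of the progenitor domains, Ebf2 (10.2 kb) of motor neurons, Ebf3 (17.1 kb) and Ebf1 (10.1 kb) of early neurons, and Ptch1 (9.79 kb), the Hedgehog receptor, and Wnt7b (8.43 kb). Each of these lists was higher than random lists in a two-sided permutation test with 100000 resamples (adjusted p = 4.2e-05, which rests on the smallest p the resamples can give, 2e-05).

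Breadth was lower for genes of several other tissues. Liver genes had 0.396 kb (adjusted p = 4.2e-05, permutation test), pluripotency and germline genes 0.634 kb (0.000455), heart genes 0.939 kb (0.0381) and blood genes 0.951 kb (0.0161). Afp and Ahsg of liver, Myh6 and Myh7 of heart, Alas2 of blood and Acrv1 of sperm had 0 kb covered in the replicated list and in both replicates. Other unmarked members had some length covered, 0.96 kb at Aif1 of microglia and 1.52 kb at Ddx4 of germ cells. Klf1, an erythroid transcription factor (5.27 kb), and Epor, the erythropoietin receptor (4.40 kb), led the blood list. Apoa2 (2.05 kb) and Fgb (1.92 kb) led the liver list, Hcn4 (3.37 kb) and Tnni3 (2.98 kb) the heart list, and Utf1 (2.73 kb) and Tdgf1 (1.95 kb) the pluripotency and germline list, all above the mean of random lists. Against random lists matched on promoter CpG class and on neighbouring TSSs the blood (adjusted p = 0.851) and heart (0.186) calls were lost in the same permutation test, and liver (0.0475) and pluripotency (0.00049) passed.

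Somite genes, at 3.67 kb (adjusted p = 0.000614), neural crest genes, at 3.59 kb (0.00141), and housekeeping genes, at 3.84 kb (0.000305), had more covered length than random lists in the permutation test. The somite list was led by Uncx, a transcription factor also known from spinal interneurons (12.3 kb), and Foxc1 (10.3 kb), and the crest list by Pou4f1 (9.06 kb) and Tfap2a (8.13 kb). Pou4f1 and Foxd3 of the crest list are also in the spinal interneuron list, and Isl1 and Phox2b in the motor neuron list. Eef2 (8.198 kb) and Rpl13a (7.75 kb) led the housekeeping list. Forebrain and midbrain genes, although mostly marked at the promoter, had 2.13 kb (adjusted p = 0.481, permutation test), with at most 4.63 kb at Otx1 and 4.06 kb at Dlx2. Glial genes had 2.27 kb (0.386), led by Nfia (8.71 kb) and Pdgfra (8.48 kb), notochord and endoderm genes 1.51 kb (0.481), epidermal genes 1.47 kb (0.396) and endothelial genes 1.33 kb (0.248), none of them set apart by the permutation test. In permutation tests against matched lists the glial call was gained (adjusted p = 0.017), and with a window of 25 kb the crest (0.0656), blood (0.175) and heart (0.115) calls were lost.

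**Figure D2:**
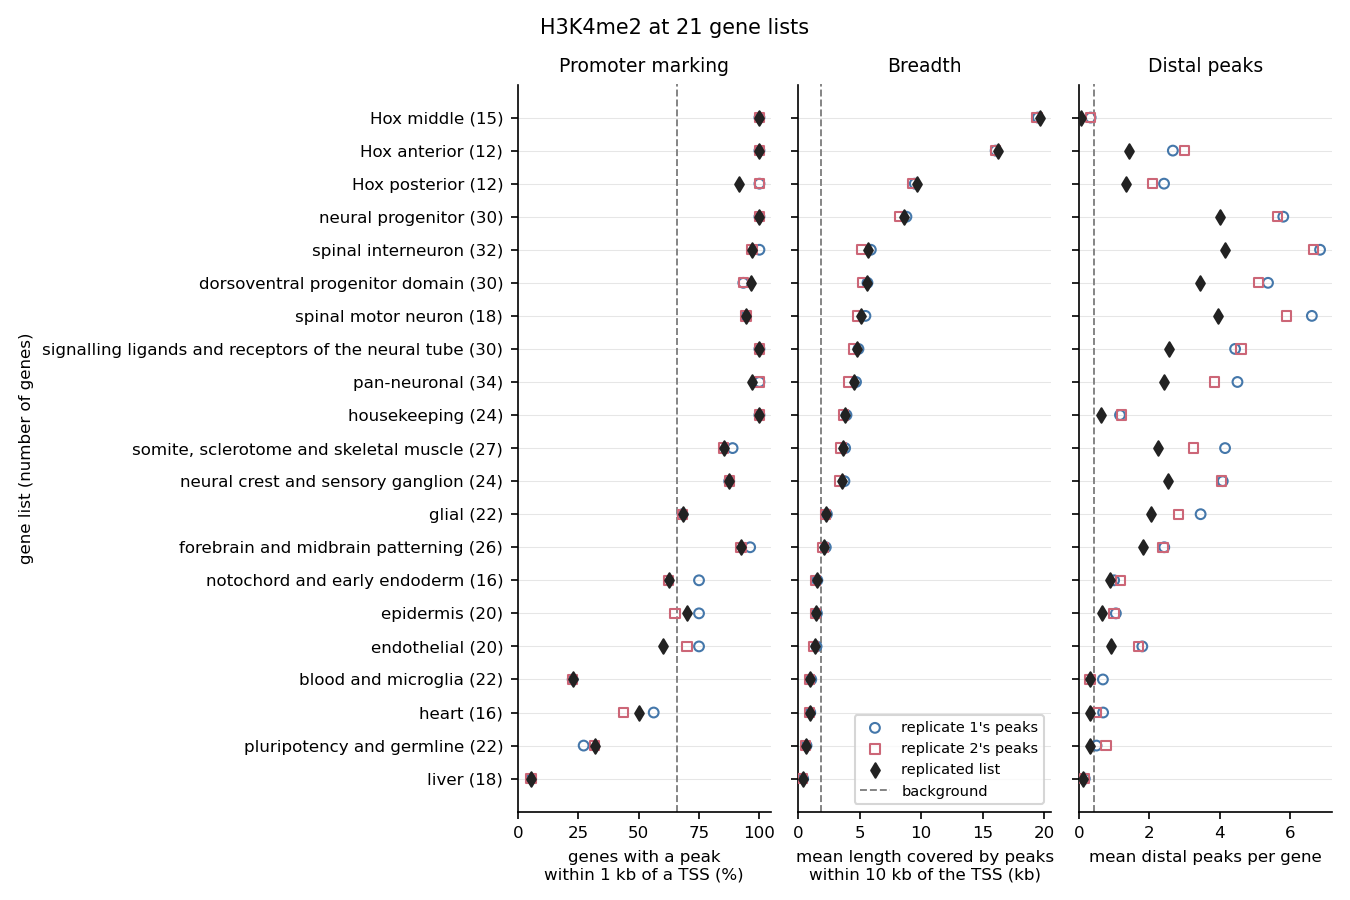
Each line is 1 of 21 gene lists, with its number of genes. The panels give the percentage of genes with a peak within 1 kb of a TSS, the mean length in kb covered within 10 kb of the 5'-most TSS, and the mean number of distal peaks per gene, for the replicated list and each replicate's own peaks, with a dashed line at the value of all genes or of random lists. The Hox and neural progenitor lists have the most covered length, at 8.64 to 19.6 kb, and the liver list the least, at 0.396 kb.

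Hox genes specify position along the body axis, and those of groups 1 to 9 had the longest coverage around the TSS among the lists. Genes of groups 5 to 9 had 19.6 kb of the 20.001 kb window covered (SD 0.513 over 15 genes), groups 1 to 4 had 16.2 kb (SD 6.53 over 12 genes) and groups 10 to 13 had 9.64 kb (SD 7.03 over 12 genes), each above random lists in the permutation test (adjusted p = 4.2e-05). Hoxa2, Hoxa3, Hoxa5 and Hoxa6 had 20.001 kb covered. Genes of 1 cluster share peaks, so their values are not independent. With 1 value per cluster, an analysis added after the data were seen, the 4 clusters averaged 19.6 kb for groups 5 to 9, 16.8 kb for groups 1 to 4 and 8.23 kb for groups 10 to 13, and each stayed above random lists (adjusted p of at most 0.0002, permutation test). By that count groups 10 to 13 lay below the neural progenitor genes (8.64 kb).

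Within the clusters the covered length fell off toward the groups of the tail end. The mean of groups 10 to 13 was 0.532 of that of groups 1 to 9 (9.64 against 18.1 kb, p = 0.00012, two-sided permutation test over genes, chosen after the values were seen). Hoxc10 (18.8 kb) and Hoxd10 (18.6 kb) were still covered over most of the window, and the values dropped through Hoxc11 (13.1 kb) and Hoxc12 (2.38 kb) to Hoxc13 (0.958 kb), and through Hoxd11 (11.5 kb) and Hoxd12 (9.08 kb) to Hoxd13 (3.70 kb). Hoxa13 had 3.59 kb and Hoxb13 1.30 kb, the latter with 1.81 kb in replicate 1's own list and 2.00 kb in replicate 2's. At the other end, Hoxb1 (2.13 kb) and Hoxd1 (3.38 kb) were also narrow, while Hoxa1 had 16.3 kb. The fold of the promoter peak did not fall with covered length at every gene. It was 17.7 at Hoxd10, 6.35 at Hoxd11 and 3.73 at Hoxd12, but 18.0 at Hoxd13, 24.3 at Hoxb1 and 25.3 at Hoxd1. At Hoxa13 (11.6), Hoxb13 (6.59) and Hoxc13 (7.09) the fold was below that at Hoxa9 (38.6), Hoxb9 (45.9) and Hoxc9 (28.3). Between the outermost gene ends the replicated list covered 90.9% of Hoxa (chromosome 6, 52155590 to 52260880), 58.6% of Hoxb (chromosome 11, 96194316 to 96368256), 76.2% of Hoxc (chromosome 15, 102921103 to 103036852) and 77.0% of Hoxd (chromosome 2, 74668310 to 74765142). In replicate 1 these shares were 90.3%, 59.2%, 75.1% and 75.5%, and in replicate 2 they were 88.8%, 58.5%, 75.5% and 74.1%. The Hoxb span includes the stretch from Hoxb13 (TSS at 96194316) to Hoxb9 (96271457), which holds no other Hox gene. By length Hoxb was the most covered in the replicated list, with 101.9 kb against 95.7 kb at Hoxa, 88.2 kb at Hoxc and 74.5 kb at Hoxd.

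**Figure D3:**
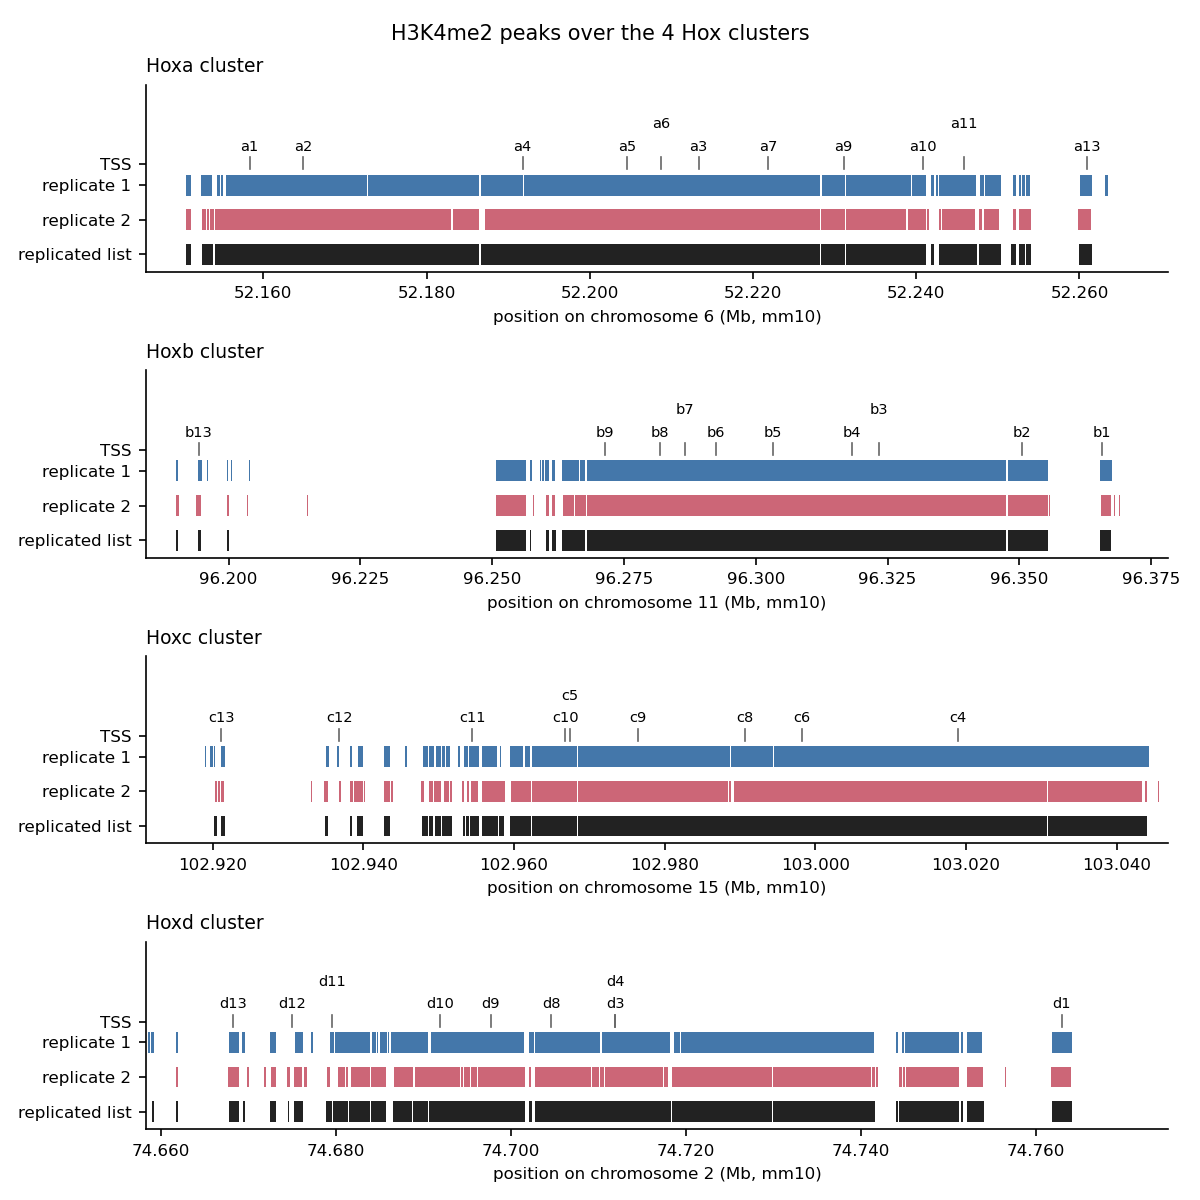
Map of the Hoxa, Hoxb, Hoxc and Hoxd clusters with 10 kb on each side, against position in Mb on mm10. Bars are peaks of replicate 1, replicate 2 and the replicated list, and ticks mark the 5'-most annotated TSS of each gene, which for Hoxa3, Hoxc5 and Hoxd3 lies at or among neighbouring genes. Coverage is nearly continuous over the middle of each cluster and broken toward the 13 end. There Hoxc13 has 0.958 kb and Hoxb13 1.30 kb within 10 kb in the replicated list.

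Of the replicated peaks, 10901 (35.4%) were distal, more than 1 kb from every annotated TSS, and 9607 of these had their nearest protein-coding TSS within 100 kb, a mean of 0.438 per gene. Neural genes had the most of them. Spinal interneuron genes had 4.16 distal peaks each (SD 3.87 over 32 genes), neural progenitor genes 4.00, motor neuron genes 3.94, dorsoventral genes 3.43, signalling genes 2.57, crest genes 2.54 and pan-neuronal genes 2.41, all above random lists (adjusted p = 6e-05, two-sided permutation test). The replicates' own lists, which keep more weak peaks, gave higher means, with 6.84 and 6.66 for interneuron genes, 5.8 and 5.63 for progenitor genes, 6.61 and 5.89 for motor neuron genes, 5.37 and 5.1 for dorsoventral genes, 4.43 and 4.6 for signalling genes, 4.08 and 4.04 for crest genes and 4.5 and 3.85 for pan-neuronal genes. In the same permutation test somite genes had 2.26 (adjusted p = 0.000157), glial genes 2.05 (0.00122) and forebrain and midbrain genes 1.81 (0.00121). Their means in the replicates' own lists were 4.15 and 3.26, 3.45 and 2.82, and 2.42 and 2.38. With peaks of −log10 q of at least 5 interneuron genes had 2.53, progenitor genes 2.4, dorsoventral genes 1.77 and motor neuron genes 1.61 (adjusted p of at most 0.00028, permutation test). Fewer peaks were counted for random lists there as well, so these lower means do not show a smaller excess. The excess did shrink against matched lists. Against lists matched on the span between neighbouring TSSs the ratio to random lists was 5.76 in place of 9.51 for interneuron genes, 6.04 in place of 9.13 for progenitor genes, 5.81 in place of 9.02 for motor neuron genes and 4.85 in place of 7.86 for dorsoventral genes (adjusted p = 8.4e-05, permutation test). Single genes with many distal peaks were Uncx with 16, Foxc1 and Ptch1 with 10, and Lhx5, Ebf3 and Ebf1 with 8 each. No list was called lower than random lists, nor did any pass as lower at an unadjusted p under 0.05 in that permutation test. The lower bound of the random range was 0.0556 for the liver list and 0 for Hox groups 1 to 4 and 10 to 13. Lists this short therefore had little room to be called lower. Liver, heart, blood, pluripotency and Hox group 5 to 9 genes lay below the random mean without passing. In that permutation test liver genes had 0.111 (adjusted p = 0.229), heart genes 0.313 (0.866), blood genes 0.318 (0.829), pluripotency genes 0.318 (0.829), housekeeping genes 0.625 (0.472), epidermal genes 0.650 (0.472), notochord and endoderm genes 0.875 (0.229) and endothelial genes 0.9 (0.188). Hox groups 1 to 4 (1.42, adjusted p = 0.0595) and 10 to 13 (1.33, 0.0786) passed the permutation test against lists matched on the span between neighbouring TSSs (adjusted p = 0.00126 and 0.00393). Groups 5 to 9 had 0.0667 (adjusted p = 0.208, permutation test), and 0.333 with each replicate's own list. Groups 1 to 4 also passed with each replicate's own list (2.67 and 3, adjusted p = 0.0355 and 0.0126), and groups 10 to 13 with a limit of 50 kb (adjusted p = 0.0464) but not with the replicates' own lists (2.42 and 2.08, 0.0577 and 0.083), by the same permutation test. In the replicates' own lists the means were also higher for heart (0.688 and 0.5), housekeeping (1.17 and 1.21), endothelial (1.8 and 1.7), epidermal (1.05 and 1) and pluripotency genes (0.5 and 0.773), and for blood genes in replicate 1 (0.682).

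Joining replicated peaks within 1 kb gave 23207 regions with a median length of 1465 bp. The 4 longest were the Hox clusters, with 97.9 kb at Hoxa (chromosome 6, 52152487 to 52250369), 92.3 kb at Hoxb (chromosome 11, 96263179 to 96355509), 90.8 kb at Hoxc (chromosome 15, 102953217 to 103044000) and 62.7 kb at Hoxd (chromosome 2, 74678887 to 74741586). Then came Pou3f3 (31.1 kb, chromosome 1, 42683954 to 42715025), Nr2f2 (25.7 kb), a nuclear receptor, Pax6 (24.5 kb, chromosome 2, 105666960 to 105691506), Zfhx3 (24.005 kb), Zic4 with Zic1 (23.5 kb), Pou3f2 (22.6 kb), Ptch1 (22.4 kb) and Sox2 (21.4 kb, chromosome 3, 34647922 to 34669347). Skida1 with Mllt10 (20.7 kb), Ebf3 (19.95 kb), Meis2 (17.5 kb), Pax3 (17.3 kb), Pax7 (16.8 kb) and Bahcc1 (16.7 kb) completed the regions with a protein-coding TSS. The remaining 2 held none, a region of 29.3 kb (chromosome 13, 83713453 to 83742719) that contains the microRNA gene Mir9-2 and long noncoding RNA genes, and one of 20.9 kb (chromosome 3, 88199665 to 88220534) that contains Mir9-1. Each of the 20 regions was covered to at least 72.8% by each replicate's own peaks. Without joining, 9 of the 20 overlapped the 20 longest single peaks.

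The pools differed at few promoters. Of the protein-coding genes 14479 were marked in both replicates, 175 in replicate 1 only and 134 in replicate 2 only, so that 97.9% of the genes marked in either were marked in both. The median fold of the promoter peak was 3.48 for genes marked in replicate 1 only and 3.32 for those in replicate 2 only, against 21.4 and 18.99 in the same lists for genes marked in both. Of the listed genes 9 were marked in replicate 1 only. Those with the highest fold were Lor (30.3), an epidermal gene, Tbr1 (5.92), Evx2 (4.68), an interneuron factor, Pdx1 (4.33) and Myl7 (4.10). The Lor peak was itself overlapped by a replicate 2 peak whose edge lay more than 1 kb from the TSS, and the peaks at Tbr1, Evx2, Pdx1 and Myl7 had no counterpart in replicate 2. Dppa3 (2.98), a germline gene, was the listed gene marked in replicate 2 only, and its peak was likewise overlapped by a replicate 1 peak. With 1 sample on each side these differences were not tested.

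Among 7 strings of transcription factor sites, CAGCTG, an E-box bound by basic helix-loop-helix factors, had the highest ratio in distal peaks, though not beyond all strings of the same letters. It occurred 0.872 times per kb within 200 bp of the midpoint of the 10901 distal peaks and 0.546 times per kb in flanks 2000 to 2400 bp away, a ratio of 1.596, which ranked 4 among 42 arrangements of the same letters without a CG, the highest of which reached 1.66. The homeodomain core TAATTA had a ratio of 0.917, below 1, and ranked 1 of 14, since all its rearrangements were more depleted (median 0.622). The E-box CAGATG had 0.963 (rank 42 of 120), the Sox string CATTGT 0.897 (29 of 100), the Rfx string TTGCCA 1.02 (28 of 120), the Gata string GATAAG 0.821 (33 of 60) and the AP-1 string TGACTCA 0.863 (179 of 450). Ranks compare strings of equal base composition and are not tests across replicates. In the replicates' own lists CAGATG had ratios of 1.05 and 1.04, on the other side of 1.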

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

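Of the tests in this part, the distal peaks and promoters of mesenchymal genes and the Hox genes within 2.5 kb were chosen only after the related values were seen, and the matched lists, fixed before the data were examined, were put to use on cluster density only then.

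Outside the assembled chromosomes used for all gene results, 13 replicated peaks lay on 5 unplaced or unlocalized scaffolds. The scaffold GL456233 assigned to chromosome X held 5 of them, with folds from 5.43 to 8.71, and 12 of the 13 were overlapped by peaks of both replicates.

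The peaks found in 1 pool alone were weighed against the calling threshold and against a difference in tissue content. At least 99.2% of them in each list had a fold below the median of their own list (99.7% in replicate 2), which is consistent with weak peaks near the calling threshold. In the strongest fold quartile 0% of the peaks in either list were unshared, so no peak of that strength was found in 1 pool alone. This can say little about tissue content. In the replicated list 89.2% of the strongest quartile lay at promoters, and 98.7% of genes with a CpG-rich promoter were marked. A difference that changed folds without removing a peak would not show in overlap. Among peaks below the median fold, those unshared had a gene of the 7 lists of other tissues as nearest gene in 1.03% of cases in replicate 1, against 1.14% of the shared ones (p = 0.467, two-sided Fisher exact test), and in 0.687% against 0.987% in replicate 2 (p = 0.0195, the same exact test), in neither pool more often. A difference in tissue content that changed folds, or added weak peaks at genes outside these lists, stays open.

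Genes of other tissues (endothelium, blood, liver, heart, epidermis, somite, notochord and endoderm) were marked at many promoters, and CpG-rich promoters or cells of those tissues could account for this. Of these genes, 32 of 34 with a CpG-rich 5'-most promoter were marked (94.1%) and 38.8% of the 103 others; with every TSS counted, 41 of 43 with a CpG-rich promoter and 33.0% (95% exact interval 23.6 to 43.4) of the 94 without one, beside 31.7% of other protein-coding genes without one, so CpG content goes with the marking and leaves 31 marked genes without such a promoter. The CpG-poor promoters of the 7 lists were not told apart from those of other genes (38.8% against 39.96%, p = 0.841, two-sided Fisher exact test), a pooled share that covers a higher one in the somite list (10 of 14, adjusted p = 0.0445) and a lower one in the liver list (1 of 18, adjusted p = 0.00903). For mesenchymal cells beside the neural tube, 19 mesenchymal transcription factor and matrix genes outside the 21 lists had 0.947 distal peaks each (1.47 and 1.84 in the replicates' own lists) against 0.737 in lists matched on the span between neighbouring TSSs (p = 0.514, two-sided permutation test), from 4 each at Osr1 and Col12a1 to 0 at 11 genes such as Lum, Postn and Dcn. At promoters 10 of the 14 with a CpG-poor one were marked, against 39.9% of other genes (p = 0.0254, two-sided Fisher exact test). With every TSS classed, 7 of 11 were marked (p = 0.0444, two-sided Fisher exact test). Of the 10, Dcn, Fap and Col6a1 had weak peaks (folds of 3.03, 3.85 and 3.85), and the others had folds of 12.1 or more. The matrix genes Col3a1, Col6a3, Lum and Postn were unmarked. Against CpG-poor promoters 11 of the 21 lists were marked more often, among them the forebrain and midbrain and the housekeeping lists. Such a share is therefore not specific to mesenchymal genes. Neither the promoters nor the distal peaks decide whether mesenchymal cells were in the pool, and marking of the same promoters in neural cells was not tested.

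The breadth around Hox genes was weighed against the density of the clusters. Random lists matched on promoter CpG class and on the number of neighbouring TSSs stayed far below it, with the 3 Hox lists at 3.69 to 6.14 times their mean (adjusted p of at most 4.67e-05, permutation test), so density as matched here does not account for the whole of it. The smaller breadth of groups 10 to 13 was also weighed against windows that reach past a cluster's end. Within 2.5 kb of the TSS their mean was 0.549 of that of groups 1 to 9 (2.62 against 4.77 kb, p = 1e-05, the smallest this permutation test can give). Such windows therefore do not account for the whole of it. A part stays possible, because the TSSs of Hoxa13, Hoxb13, Hoxc13 and Hoxd13 lie at the cluster ends and part of their 2.5 kb windows lies outside. The p-value is over genes, which share peaks within a cluster. A smaller share of cells with active tail-end Hox genes in these pools is one biological reading of 0.549. It was not tested, since the labels give no position along the axis and do not say which part of the neural tube was taken.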

How the results depend on the processing

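The basic annotation and the CpG-poor background for promoter marking and 1 value per Hox cluster were chosen only after the results were seen; the other alternatives were not. No paired analysis was possible because there is 1 group. Leaving out 1 replicate means using the other replicate's own list, which has more weak peaks. Depth is unknown, so its effect could not be examined, and except where the alternative's construction shows it, the cause was not tested.

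With −log10 q of at least 5, replicate 1 kept 26372 peaks and replicate 2 25945, the shared percentages were 89.3 and 94.1, 99.8% of pooled peaks were in the replicated list, and 70 promoters (134 before) were marked in replicate 2 only. With 50% of the peak covered 65.7% and 73.8% were shared, with reciprocal overlap 58.1% and 59.98%, and with the 21206 strongest peaks of each list 93.7% and 96.1%.

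The promoter share was 45.8% at 500 bp, 71.6% at 2.5 kb, 69.7% with −log10 q of at least 5, 55.8% in the pooled list and 49.2 to 51.4% leaving out a replicate. In the same order the exon share was 7.67, 2.44, 4.03, 4.98 and 5.23 to 5.31%, the intron share 28.6, 12.0, 12.9, 22.5 and 25.6 to 27.4%, and the intergenic share 17.9, 14.0, 13.4, 16.7 and 17.7 to 18.2%.

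The number of lists marked more often was 11, and 10 to 13 in the alternatives other than CpG-rich promoters only, where it was 0 because 98.7% of that background was marked. There the dorsoventral list (95.2%, adjusted p = 0.748) and the forebrain and midbrain list (93.3%, adjusted p = 0.665) lay below the background without passing the Fisher exact test, while the notochord and early endoderm list (71.4%, adjusted p = 0.0308) and the pluripotency and germline list (33.3%, 7e-06) passed as lower. Against CpG-poor promoters only, 11 lists were marked more often and 1, the liver list, less often, against 3 before: the blood list (22.7%, adjusted p = 0.157) and the pluripotency and germline list (31.2%, 0.643) did not pass the exact test there, nor did the motor neuron and interneuron lists (83.3% each, 0.061). The call was gained there by Hox groups 10 to 13 (5 of 5, adjusted p = 0.0237) and by the somite list (10 of 14, 0.0445), in the same exact test. The number of lists with more breadth was 12, and 11 to 13 in the alternatives, and the number with less was 4, against 2 with a 25 kb window and 2 with matched lists. The number with more distal peaks was 10, and 10 to 12 in the alternatives. For single lists, 179 of 208 alternatives for promoter marking, 144 of 150 for breadth and 121 of 126 for distal peaks kept the call of higher, lower or neither. Among lists without a call the direction changed in some alternatives, for marking in the glial, notochord and endoderm, endothelial and epidermal lists and others, for breadth in the forebrain and epidermal lists and for distal peaks in the heart and pluripotency lists. Without joining, 9 of the 20 longest regions remained among the 20 longest.

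With the whole peak CAGCTG had a ratio of 1.51, CATTGT 0.844 and TTGCCA 0.998, the last on the other side of 1. Leaving out a replicate gave 1.04 to 1.05 for CAGATG, on the other side of 1, 1.47 to 1.49 for CAGCTG, 0.971 to 0.973 for CATTGT, 1.08 to 1.09 for TTGCCA, 0.896 to 0.912 for GATAAG and 0.955 to 0.974 for TGACTCA.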

Other observations

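The test of microRNA genes in this part was chosen only after the regions at Mir9-1 and Mir9-2 were seen.

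Several of the microRNA genes known from neural tissue lay in broad H3K4me2 regions, and others had no covered length. Within 10 kb on each side, replicated peaks covered 17.1 kb at Mir9-3 (chromosome 7, 79505264 to 79505353), 14.2 kb at Mir9-1 and 14.2 kb at Mir9-2, the 3 genes of the neural progenitor microRNA miR-9. They covered 12.2 kb at Mir124a-2, 8.56 kb at Mir124a-3 and 7.69 kb at Mir124a-1, the genes of a microRNA known from neurons, 9.64 kb at Mir219a-1 and 5.54 kb at Mir137. Both replicates' own peaks gave values near these, such as 17.3 and 16.8 kb at Mir9-3 and 12.0 kb in each at Mir124a-2. Mir218-1 and Mir218-2, microRNAs of motor neurons that lie in introns of Slit2 and Slit3, had 0 kb, Mir128-1 and Mir153 also had 0 kb, and Mir128-2 had 1.21 kb. At the muscle microRNAs Mir206, Mir133b, Mir133a-1 and Mir1a-2, the heart microRNAs Mir208a and Mir208b and the liver microRNA Mir122 0 kb was covered, while Mir1a-1 of muscle had 1.53 kb. Other genes of the non-neural set had 4.40 kb (Mir142 of blood cells), 2.67 kb (Mir141 and Mir200c of epithelia), 1.89 kb (Mir126a of endothelium), 1.61 kb (Mir144 and Mir451a of erythroid cells), 1.49 kb (Mir375) and 1.06 kb (Mir203).

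The hypothesis that breadth at microRNA genes goes with the tissue a microRNA is known from was tested on 11 neural genes, without the Mir9 genes that prompted it, and 21 genes of other tissues. The neural genes had 4.48 kb covered (SD 4.53) and the others 0.903 kb (SD 1.25), beside a mean of 1.11 kb over 2202 annotated microRNA genes (p = 0.00342, two-sided permutation test). Several of these genes lie beside each other or inside protein-coding genes, so breadth may in part belong to a host or neighbouring gene. Neighbours such as Mir141 with Mir200c (2.67 kb each) and Mir144 with Mir451a (1.61 kb each) entered the test as separate genes. The p-value therefore treats values as independent that are not.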
